A study of Marchantia polymorpha with 24 samples.

How the data were processed

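RNA was sequenced from whole plants of Marchantia polymorpha in 24 libraries: Tak-1, NahG and tga plants, mock treated or dipped in Pseudomonas syringae pv. tabaci (Pta) 11528, at 24 h, and Tak-1 also at 72 h. RNA came from an RNeasy Plant Mini Kit with DNase digestion on the column, and libraries were prepared by Novogene for Illumina sequencing, per the labels' protocols. The values were deposited by the authors as 1 table of TPM (a transcript measure scaled for gene length and library size) with 18349 genes and 24 columns, per the file headers. Reads were trimmed with fastp, per the submitters' processing notes, with no version. The aligner, the counter and the genome build are not given in the sources used here. Columns were matched to samples by the library names in the labels. Each group holds 3 libraries, which the labels call biological replicates.

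The table as deposited had lost the decimal marks of most values, so that the digits of a number were kept but not its size. Of 440376 cells 283456 had no mark. Most of these values end after 6 decimals, and 9.94% were read as ending earlier because trailing zeros were dropped. The place of the mark was chosen jointly for the 3 libraries of a group, as the most probable one given the gene's level in the group and in the other groups. The group labels thus enter the restoration, which draws replicates together where a mark is in doubt. A last step used the fact that TPM of a column add up to 1000000 and changed 32 cells. Of these, 25 were in mock Tak-1 replicate 3 at 72 h, which exceeded that sum by more than any other library and where the most doubtful cells were lowered until it no longer did. After this step 16 of 24 columns added up (16 of the 18 at 24 h), against 9 before it, and the largest shortfall of the others was 158.2 TPM. The columns at 24 h that did not add up were infected NahG replicates 1 and 2, short by 40.76 and 44.01 TPM. With 6 decimals in each cell the columns would have summed to 868153 to 933713. In 131 cells of 83 genes the chosen place had a probability under 0.9. All of these lay in columns that did not add up, because marks in a column that added up were taken as certain. In 3 simulations of the lost marks, 50 of 283428, 44 of 283450 and 38 of 283439 cells were restored wrongly, none of them in a column that added up, and most of them at 72 h. Of these wrong cells 29, 19 and 20 had a probability over 0.9, so that limit does not remove all misplaced marks. The simulations started from the restored values, so they cannot show how many marks the restoration itself misplaced. The restoration was revised after a first look at the genes with the largest changes, which held misplaced marks, and its spreads were then chosen by how closely the columns added up to 1000000, not by any test between groups. The first pass, which differs in 91 cells, and the omission of the 83 genes are among the alternatives. TPM keeps no depth, so the depth of each library is unknown, no counting interval can be given and a low value cannot be given a floor.

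Gene symbols came from the reference assembly MpTak2_v7.1, which was matched by locus number. It has an entry for 17411 of the 18349 genes and a symbol for 3093. The build of the table is not named, so no coordinates are given, and the reference was used only for names and neighbours.

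Genes at 1 TPM or more in at least 3 libraries (12545) were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 mean per group over all 8 groups, empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. All log2 changes are on the log2(TPM + 1) scale, which understates changes of genes at low levels. The 13 comparisons were infected against mock in Tak-1 at 24 h and at 72 h, in NahG and in tga, NahG and tga against Tak-1 in mock and in infected plants, the differences of responses between lines and between times, and mock Tak-1 at 72 h against 24 h. Gene lists were tested with camera of limma at a preset correlation of 0.01, with camera at an estimated correlation and fry beside it, adjusted over the lists of a comparison. The correlation was estimated from the spread within groups over all 24 libraries, those at 72 h included, whichever groups were compared. A list passed by camera with the preset correlation. Fry, which asks whether a list changed at all and not whether it did so more than other genes, passed 7 lists in Tak-1 at 24 h (camera 7), 16 in Tak-1 at 72 h (6), 8 in NahG (5) and 0 in tga (2). Against Tak-1 it passed 2 in mock NahG (4), 4 in mock tga (5), 8 in infected NahG (6) and 4 in infected tga (8). For differences of responses it passed 0 for NahG less Tak-1 (4), 1 for tga less Tak-1 (8), 1 for tga less NahG (5) and 16 for 72 h less 24 h (7), and between mock plants 25 (11). Of the lists, 30 were written before the data were examined and 2 (cupins and DOXC dioxygenases) were added later. The lists had been written as words of gene descriptions and were turned into families of gene symbols when the reference was read, since the reference gives symbols only. Of the lists 27 had at least 3 measured genes. The lists of photosynthesis, ribosome and rhizoid genes held 1 measured gene each, the U chromosome list held 2, and no gene could be placed on the organelles. The lists of auxin, axoneme, detoxification, ERF, MYB, salicylate, V chromosome, respiratory burst and DOXC dioxygenase genes passed in no comparison (lowest camera adjusted p = 0.222, 0.123, 0.068, 0.314, 0.204, 0.111, 0.222, 0.0639 and 0.144). The test, the comparisons, the lists and the rule for named genes were otherwise chosen before the data were examined.

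Named genes followed a rule: per comparison, the 6 called genes with the largest rise and the 6 with the largest fall among those with a symbol, no overlap between the groups' libraries (not asked of differences of responses) and a mean of 5 TPM or more in the higher group. To these came up to 3 called members and 1 member not called of each list described, all TGA and NPR genes, and the 2 called genes with the largest change in TPM. An exception was added after the data were seen: genes with a compared cell of a probability under 0.9 were passed over. Genes outside the rule are said to be so.

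The limma step was tested on simulated data for the comparison of infected and mock Tak-1 at 24 h over 12545 genes. It recovered 194 of 200 seeded genes (36 of 40 at a log2 change of 0.5, 38 of 40 at -0.5 and all 40 at each of -1, 1 and 2), with 8 false calls among 12285 unchanged genes. A list of 60 genes shifted by 0.2 gave a camera p of 7.36e-34, and a list with no shift 0.818. Noise was drawn independently for each gene, so the simulation cannot check the list tests where genes of a list are correlated. Seeded genes and lists were drawn from genes at higher levels only, so recovery of genes at low levels was not tested. For the overlap of the lines' differences, 100 pairs of unchanged groups were simulated against the same Tak-1 libraries, and the Tak-1 libraries were shared out between the lines in a test chosen after the overlap was seen.

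Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 TPM, median-of-ratios scaling, quantile normalization, the replicate number as a block, robust empirical Bayes, a fit of the compared groups alone, calls with a log2 change of at least 1, leaving out each library, and leaving out the Tak-1 Pta libraries at 72 h that are numbered apart from the rest. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.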

Results

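Transcript levels were measured by RNA sequencing in whole plants of Marchantia polymorpha, a liverwort whose main body is a flat haploid thallus. The labels name 3 lines. Tak-1 is the male wild type. NahG plants are Tak-1 plants that overexpress PpNahG and are described as deficient in salicylic acid, the defence hormone that the salicylate hydroxylase NahG breaks down. The tga plants are mutants of TGA, a bZIP transcription factor that in flowering plants acts with NPR proteins in salicylate signalling. Plants of 3 weeks were dipped for 5 min in a suspension of the bacterium Pseudomonas syringae pv. tabaci (Pta) 11528 (OD600 of 0.2, 0.04% Silwet L-77) or were mock treated. All 3 lines were sampled at 24 h and Tak-1 also at 72 h, giving 8 groups of 3 libraries and 24 libraries in all. The labels call the libraries of a group biological replicates. The p-values rest on the spread between libraries within groups, pooled for each gene over all 8 groups and not over the compared groups alone. At 24 h they thus also carry the spread at 72 h. For 91 infection-responsive genes the median SD was 0.332 over 8 groups and 0.21 over the 4 of NahG and Tak-1 at 24 h. The p-values at 72 h in turn draw on the spread at 24 h. Mock Tak-1 at 72 h varied widely in such genes, so SE and p-values there can be too small. The library names put 2 of the 3 infected Tak-1 libraries at 72 h (replicates 2 and 3) in a number series apart from all others. Between 14564 and 15326 of 18349 listed genes were above 0 TPM in a library, and 12545 were tested. The depth of sequencing is unknown, because TPM keeps none.

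Correlations of log2 values between replicates (across genes, which are not independent replicates) lay from 0.9951 to 0.9966 in the groups at 24 h and fell to 0.9793 between mock Tak-1 libraries at 72 h. The first principal component held 64% of the variance and set the 6 libraries at 72 h apart from the 18 at 24 h. The 93 genes of the male V chromosome summed to 1050 to 1420 TPM per library, with 27 to 31 genes at 1 TPM or more. Of the 47 genes of the female U chromosome, 2 reached 1 TPM in each library. The 47 genes still summed to 423 to 703 TPM per library, with MpUg00330 alone at 656 ± 6.14 TPM in mock Tak-1 at 24 h. The 3 lines were thus alike in this check of their male background. Genes of large families with near-identical copies (peroxidases, polyphenol oxidases, dirigent proteins, LEA-like proteins) are uncertain one by one, since reads could be divided between copies.

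The targeted gene came first. TGA, named MpBZIP8 (Mp2g13330), was read at 54.6 ± 0.53 TPM in mock Tak-1 plants at 24 h and at 70.2 ± 1.31 TPM in mock tga plants (mean ± SD, n = 3), and all tga libraries lay above all Tak-1 mock libraries. The difference was 0.36 on the log2(TPM + 1) scale (SE 0.06, limma with Benjamini-Hochberg adjustment, adjusted p = 0.000235). The kind of mutation is not given in the sources used here, so a transcript that is present neither checks nor contradicts the label of the mutant. The other groups at 24 h stood at 63.4 ± 3.02 TPM in infected Tak-1, 58.7 ± 3.32 in mock NahG, 65.3 ± 0.95 in infected NahG and 72.9 ± 2.36 in infected tga plants. At 72 h the values were 81.7 ± 0.625 TPM in mock and 87.1 ± 9.14 in infected Tak-1. MpBZIP8 rose with infection in Tak-1 at 24 h by 0.21 (limma adjusted p = 0.0223), but without single libraries adjusted p ran from 0.0185 to 0.108 and the call was lost without mock replicate 1, 2 or 3 or infected replicate 2 or 3. Infected tga plants exceeded infected Tak-1 by 0.2 (limma adjusted p = 0.0246), a call lost without Tak-1 Pta replicate 1 or tga Pta replicate 2 or 3 (adjusted p from 0.0318 to 0.126 without single libraries).

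The salicylate list held 5 measured genes, and passed the list test in no comparison. MpNPR (Mp1g02380) rose in Tak-1 at 72 h from 12.8 ± 0.216 to 16.4 ± 0.383 TPM (log2 change 0.33, limma adjusted p = 0.000722). At 24 h it was not called in any line, with 7.75 ± 0.658 TPM in mock and 8.82 ± 0.896 TPM in infected Tak-1 (limma adjusted p = 0.212). MpICS (Mp2g20660), the isochorismate synthase gene of salicylate synthesis, was called with infection in no line and at no time (9.84 ± 0.545 TPM in mock and 12 ± 0.845 TPM in infected Tak-1 at 24 h, limma adjusted p = 0.0885), and was picked for its role after its values were seen. Its means were 10.9 and 12.3 TPM in mock and infected NahG, 10.4 and 10.6 TPM in tga, and 7.64 and 8.15 TPM in Tak-1 at 72 h. MpEDS5 (Mp1g04370) fell in infected Tak-1 at 72 h, to 62.5 ± 1.54 TPM from 79.7 ± 18.1 TPM in mock (limma adjusted p = 0.00585), a call lost without mock replicate 1 (adjusted p = 0.0572, the highest of a range from 4.55e-06 without single libraries).

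**Figure D1:**
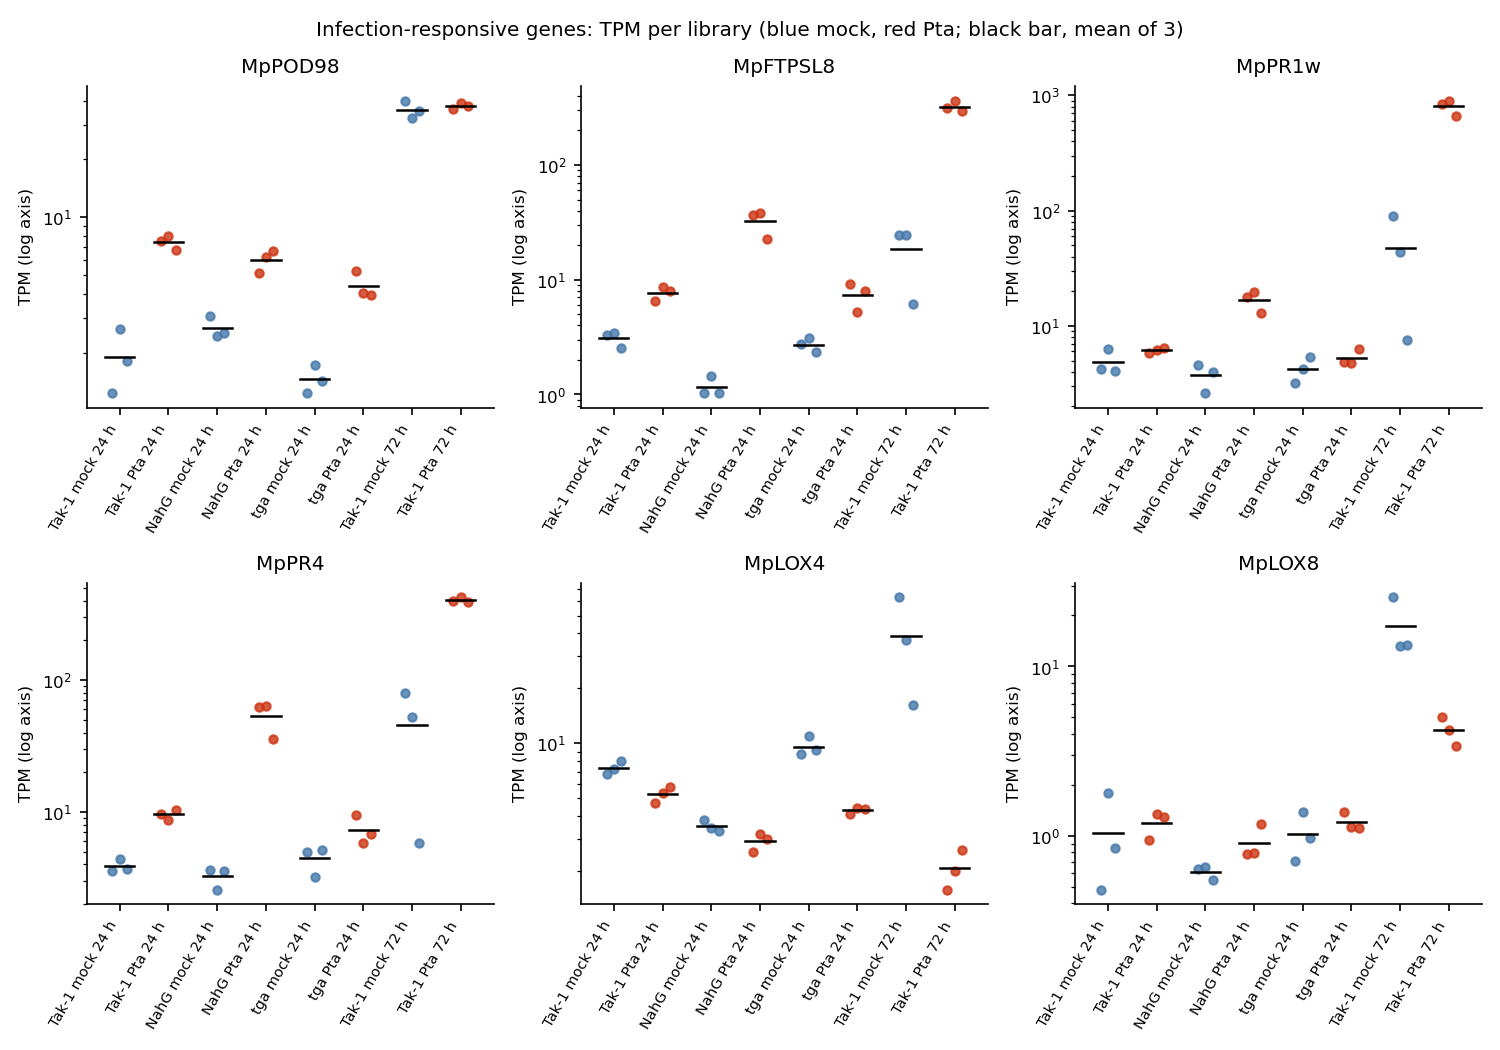
TPM on a log axis of 6 genes in each of the 24 libraries (blue, mock; red, Pta), with a black bar at the mean of 3 libraries. MpPR1w reached 801 TPM in infected Tak-1 at 72 h against 47 TPM in mock plants, while MpPR4 stood at 53.8 TPM in infected NahG and 9.57 TPM in infected Tak-1 at 24 h.

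The first question was what infection changes in the wild type at 24 h. The secreted class III peroxidase MpPOD98 (Mp5g13650) had the largest rise among named genes. It rose from 1.9 ± 0.705 to 7.42 ± 0.624 TPM (log2 change 1.57, SE 0.14, n = 3, limma adjusted p = 8.58e-07) and another peroxidase, MpPOD155 (Mp7g14950), from 2.38 ± 0.616 to 5.85 ± 0.439 TPM (1.03, limma adjusted p = 0.000209). MpCupin71 (Mp5g00990), of the cupin family, rose from 7.61 ± 1.18 to 16.6 ± 2.22 TPM. Less firm were the rises of the GH19 family chitinase gene MpGH19.6 (Mp4g20440), from 5.2 ± 0.731 to 16.1 ± 3.18 TPM (1.45, limma adjusted p = 0.0218, from 0.0315 to 0.0872 without single libraries), and of MpFTPSL8 (Mp3g19720), of the terpene synthase list, from 3.08 ± 0.491 to 7.7 ± 1.09 TPM (1.09, limma adjusted p = 0.0394, from 0.06 to 0.141). The call of MpGH19.6 was lost without mock replicate 1 or 3 or Pta replicate 2 or 3, and that of MpFTPSL8 without each single library. The dehydrin MpDHN2 (Mp4g06390) fell from 42.5 ± 4.09 to 28.3 ± 2.07 TPM (log2 change -0.57, limma adjusted p = 0.00465) and the ABC transporter MpABCC13 (Mp5g13230) from 12.2 ± 1.29 to 8.06 ± 0.459 TPM. Of the 12545 genes, 957 were called, 640 higher and 317 lower, and 14 rose and 4 fell by at least 1 log2 unit.

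By list, 28 of 112 measured class III peroxidases rose and 2 fell in infected Tak-1 at 24 h (43 and 2 adjusted over the list alone), with a median log2 change of 0.27. MpPOD164 (Mp8g01700), the one with the most TPM, was not called, at 175 against 159 TPM. The list test passed (camera adjusted p = 8.17e-13) and was lost with an estimated correlation (adjusted p = 0.104). Of 37 nutrient transporters 7 rose and none fell (10 rose adjusted over the list alone, camera adjusted p = 5.51e-05, adjusted p = 0.104 with an estimated correlation). They included the phosphate transporters MpPTB2 (Mp4g16580), from 1.75 ± 0.241 to 4.41 ± 0.0627 TPM, and MpPTB3 (Mp4g16590), from 12.9 ± 1.77 to 23.6 ± 1.48 TPM. Of 77 cell wall genes 14 rose and 1 fell (20 and 2 adjusted over the list alone, camera adjusted p = 0.000595, adjusted p = 0.29 with an estimated correlation). MpGH16.16 (Mp3g10390), of the xyloglucan-modifying GH16 family, went from 7.57 ± 0.533 to 14.7 ± 0.41 TPM. Of 36 polyphenol oxidases, enzymes that oxidise phenols to quinones, 11 rose and none fell, all 11 also adjusted over the list alone. One was MpPPO10 (Mp6g17930), from 1.03 ± 0.26 to 2.34 ± 0.288 TPM. Their camera adjusted p of 0.00329 became 0.324 with genes of a mean of 5 TPM or more, ran from 0.00116 to 0.324 over 11 alternatives, and gave adjusted p = 0.141 with an estimated correlation.

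Of 68 pathogenesis-related genes, a list of PR proteins, chitinases and glucanases, 5 rose at 24 h in Tak-1 (6 adjusted over the list alone, camera adjusted p = 0.0043, adjusted p = 0.835 with an estimated correlation). MpPR1 (Mp3g14110) went from 0.251 ± 0.139 to 1.09 ± 0.134 TPM and the chitinase-family gene MpGH19.15 (Mp7g04510) from 569 ± 12.6 to 633 ± 15.8 TPM. MpGH17.4 (Mp2g08760) was not called, at 303 against 288 TPM (limma adjusted p = 0.504). Of 76 cytochrome P450 genes 10 rose and 2 fell (17 and 4 adjusted over the list alone). Among them MpCYP707A (Mp2g25940), of the family that inactivates abscisic acid, rose from 0.814 ± 0.064 to 2.11 ± 0.463 TPM. Their camera adjusted p of 0.034 ranged from 0.0224 to 0.332 over 11 alternatives, with adjusted p = 0.29 with an estimated correlation. The list of cell division and histone genes shifted down (median -0.11 over 47 genes, camera adjusted p = 0.00019, adjusted p = 0.742 with an estimated correlation) although 2 of its genes were called higher and none lower, and none was called either way adjusted over the list alone. Scaling changed the balance of the calls: 66.9% were higher as deposited, 58.7% (634 higher, 446 lower) after median-of-ratios scaling and 54.7% (516 higher, 427 lower) after quantile normalization. The 957 calls became 516 without Tak-1 mock replicate 1, 535 without mock replicate 3 and 512 without Pta replicate 3.

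At 72 h the same comparison in Tak-1 was much larger. The PR-1 family gene MpPR1w (Mp7g13960) rose from 47 ± 41.3 to 801 ± 126 TPM (log2 change 4.61, SE 0.48, n = 3, limma adjusted p = 4.74e-08), MpPR4 (Mp2g21910) from 45.8 ± 37.2 to 404 ± 18.8 TPM and MpFTPSL8 from 18.4 ± 10.6 to 323 ± 36.6 TPM. MpNBS-LRR11 (Mp4g08790), an immune receptor of the NLR class, rose from 0.959 ± 0.644 to 29.2 ± 3.77 TPM, and the lectin receptor kinase MpRLK-Pelle_L-LEC26 (Mp6g03790) from 3.49 ± 1.42 to 40.4 ± 8.21 TPM. The lipoxygenase genes MpLOX4 (Mp5g21680) and MpLOX8 (Mp2g12220) fell, from 38.8 ± 23.6 to 2.06 ± 0.515 TPM and from 17.4 ± 7.18 to 4.22 ± 0.826 TPM. Of the 12545 genes 7431 were called, 4479 higher and 2952 lower, and 483 rose and 185 fell by at least 1 log2 unit. A fit without the infected libraries numbered apart called 6070 genes, but leaves 1 infected library at 72 h, whose spread then comes wholly from other groups, so it cannot exclude an effect of that series. The unnamed gene Mp7g02900 had the largest rise in TPM but a wide spread in mock, from 4470 ± 3420 to 12800 ± 427 TPM.

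Cell wall genes went down at 72 h: of 77 in the list, 40 fell and 10 rose in infected Tak-1, the same counts adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.00011, adjusted p = 0.309 with an estimated correlation). The pectate lyase MpPL1.3 (Mp3g01000) fell from 203 ± 5.56 to 76.2 ± 4.52 TPM (log2 change -1.4, limma adjusted p = 5.89e-16) and MpExpansin6 (Mp1g24230) from 214 ± 8.61 to 118 ± 5.55 TPM. Of 36 polyphenol oxidases 22 fell and 2 rose (22 and 3 adjusted over the list alone, median -0.43, camera adjusted p = 0.000246, adjusted p = 0.103 with an estimated correlation). MpPPO54 (Mp5g19990) fell from 52.6 ± 0.786 to 15.2 ± 2.77 TPM and MpPPO71 (Mp5g20040) from 66 ± 5.91 to 20.1 ± 3.48 TPM. Of 47 cell division and histone genes 26 fell and 6 rose (camera adjusted p = 0.000912, adjusted p = 0.618 with an estimated correlation). The histone genes with the lowest p went the other way: MpH2B.1 (Mp7g18140) rose from 90.2 ± 6.3 to 187 ± 2.62 TPM and MpH3.3a (Mp3g09090) from 242 ± 10.1 to 396 ± 16.4 TPM.

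Of 20 NLR genes 13 rose and 2 fell at 72 h in Tak-1, with a median of 0.55. MpNBS-LRR10 (Mp4g08290) went from 3.52 ± 1.11 to 17.7 ± 3.25 TPM, and MpNBS-LRR2 (Mp1g20580), at 24.4 TPM against 22.3 TPM, was not called (limma adjusted p = 0.0829). The list's camera adjusted p of 0.0161 ranged from 0.00445 to 0.0799 over 11 alternatives, with adjusted p = 0.618 with an estimated correlation. Of 37 nutrient transporters 18 fell and 7 rose, among them MpPTB4 (Mp4g16560), from 28 ± 2.71 to 10.1 ± 1.89 TPM (camera adjusted p = 0.0161, from 0.0141 to 0.124 over 11 alternatives, and adjusted p = 0.458 with an estimated correlation). Of 48 flavonoid genes 20 fell and 7 rose, with MpLAR-like5 (Mp8g06810) at 143 ± 0.207 TPM against 180 ± 3.12 in mock and MpPKS/CHS-like1 (Mp1g23260) higher, at 27.7 ± 2.94 against 12.9 ± 0.656 TPM. Their camera adjusted p of 0.0227 ranged from 0.0081 to 0.0894, with adjusted p = 0.618 with an estimated correlation. All 7 genes of respiratory burst oxidases and calcium signalling were called higher, but the list test did not pass (camera adjusted p = 0.0639). Most calls were higher as deposited (60.3%), but 44.2% after median-of-ratios scaling (3323 higher, 4195 lower) and 45.8% after quantile normalization (3463 higher, 4091 lower), so no balance of up and down holds for all scalings.

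The change with infection differed between 72 h and 24 h for 6047 genes (limma test of the difference, 3485 more positive and 2562 more negative at 72 h), and for 5232 genes in the fit with 1 infected library at 72 h. MpPR1w had a difference of 4.3 (SE 0.68, limma adjusted p = 2.4e-05), MpNBS-LRR11 of 3.38 and MpRLK-Pelle_L-LEC26 of 3.3. The phosphate transporters MpPTB3 and MpPTB4, higher with infection at 24 h, were lower at 72 h, with differences of -1.85 and -2.11. Polyphenol oxidases showed the same turn: 22 of 36 had a lower and 2 a higher response at 72 h, and this list passed with an estimated correlation too (median -0.73, camera adjusted p = 1.18e-06, adjusted p = 0.0174 with an estimated correlation). For cell wall genes 37 of 77 were lower and 6 higher (camera adjusted p = 2.69e-07, adjusted p = 0.087 with an estimated correlation). As deposited 57.6% of these differences were positive, after median-of-ratios scaling 43.9% (2677 higher, 3424 lower) and after quantile normalization 47% (2914 higher, 3292 lower).

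The mock Tak-1 plants at 72 h differed from those at 24 h in 6976 genes, 4988 higher and 1988 lower, with 1038 rises and 52 falls of at least 1 log2 unit. After inoculation plants were moved from agar at 16 h light to vermiculite at 8 h light, per the labels' protocols, so time since the treatment and time since this move come together, and no sample separates them. MpPOD98 stood at 36 ± 3.76 TPM at 72 h against 1.9 ± 0.705 TPM at 24 h (log2 change 3.7, SE 0.14, limma adjusted p = 5.51e-14) and the ammonium transporter MpAMT2.4 (Mp8g18510) at 21.1 ± 1.61 against 0.869 ± 0.17 TPM. MpKAI2B (Mp2g04930) fell from 107 ± 7.28 to 35.3 ± 4.74 TPM. Of 112 class III peroxidases 102 were higher and 3 lower (103 and 3 adjusted over the list alone), with a median of 1.42, and this list passed with an estimated correlation as well (camera adjusted p = 2.22e-18, adjusted p = 0.0237 with an estimated correlation). So did the polyphenol oxidases, of which 31 of 36 were higher and 1 lower (median 1.36, camera adjusted p = 7.24e-07, adjusted p = 0.017 with an estimated correlation). Of 98 genes of abscisic acid response and LEA proteins 68 were higher and 11 lower (camera adjusted p = 7.24e-07, adjusted p = 0.187 with an estimated correlation), among them MpLEA-like43 (Mp6g03100) at 118 ± 17.7 against 12 ± 1.98 TPM.

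The scaling moved the median of all genes in this mock comparison from 0.11 as deposited to 0.01 after median-of-ratios scaling and -0.09 after quantile normalization, so the changes between times are relative to a shift of that size. As deposited 71.5% of calls were higher, against 52.9% (3785 higher, 3367 lower) and 35.6% (2814 higher, 5084 lower) after the 2 scalings. The median peroxidase change of 1.42 is far above that shift. Phenylpropanoid genes (14 of 17 higher, 1 lower), nutrient transporters (26 of 37 higher, 2 lower) and cytochrome P450 genes (49 of 76 higher, 9 lower) passed in every alternative with the preset correlation (camera adjusted p = 0.00125, 0.000521 and 0.00125) and gave adjusted p = 0.384, 0.102 and 0.0956 with an estimated correlation. The oxylipin list (15 of 20 higher) and the pathogenesis-related list (47 of 68 higher) had camera adjusted p = 0.011 and 0.00798, up to 0.158 and 0.0871 over 11 alternatives, and adjusted p = 0.569 and 0.671 with an estimated correlation. Dirigent proteins and laccases, terpene synthases and WRKY factors had camera adjusted p = 0.0196, 0.0349 and 0.0395, up to 0.0525, 0.0871 and 0.158 over the alternatives, and adjusted p = 0.64, 0.102 and 0.64 with an estimated correlation. The 3 mock libraries at 72 h stood apart from each other in genes of the infection response: MpPR1w had an SD of 41.3 TPM around a mean of 47 TPM, against an SD of 126 around 801 TPM in infected plants.

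The next question was how NahG plants, with less salicylic acid by their label, respond at 24 h. MpPR15e (Mp2g01660) rose from 0.258 ± 0.0511 to 20.1 ± 7.41 TPM (log2 change 3.99, SE 0.65, n = 3, limma adjusted p = 0.000386), MpFTPSL8 from 1.17 ± 0.241 to 32.5 ± 8.38 TPM (3.92, limma adjusted p = 2.01e-07) and MpPR4 from 3.24 ± 0.581 to 53.8 ± 15.6 TPM (3.65, limma adjusted p = 0.000108). MpPOD89 (Mp5g10700) rose from 9.89 ± 0.559 to 104 ± 34.7 TPM and MpGH19.6 from 3.01 ± 0.818 to 51.8 ± 10.7 TPM. Falls were smaller, with MpCupin83 (Mp5g13860) going from 497 ± 48.1 to 270 ± 15.2 TPM (-0.87, limma adjusted p = 0.000179) and MpPL1.3 from 182 ± 4.49 to 131 ± 4.75 TPM. Of the 12545 genes 1155 were called, 907 higher and 248 lower, and 91 rose and 1 fell by at least 1 log2 unit.

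Of 13 WRKY transcription factors 5 rose and none fell in infected NahG plants (9 adjusted over the list alone, median 0.28, camera adjusted p = 0.000288, adjusted p = 0.686 with an estimated correlation). MpWRKY3 (Mp5g05560) went from 0.0965 ± 0.00792 to 2.14 ± 0.479 TPM, and MpWRKY11 (Mp1g24950), the one with the most TPM, was not called, at 452 against 399 TPM (limma adjusted p = 0.0512). Of 68 pathogenesis-related genes 17 rose and 1 fell (20 and 1 adjusted over the list alone), with a median change of 0.15 and a mean of 0.72 (camera adjusted p = 0.00203, adjusted p = 0.948 with an estimated correlation). They included MpGH18.1 (Mp1g22460), from 1.42 ± 0.231 to 6.85 ± 1.72 TPM, and MpGH19.3 (Mp2g24440), from 4 ± 0.595 to 36.2 ± 12.2 TPM. Of 37 nutrient transporters 9 rose and none fell (11 rose adjusted over the list alone, camera adjusted p = 0.00491, from 0.000571 to 0.0589 over 11 alternatives, adjusted p = 0.686 with an estimated correlation). Of 112 peroxidases 19 rose and 1 fell (24 and 2 adjusted over the list alone, camera adjusted p = 0.0359, from 5.42e-05 to 0.108 over 11 alternatives, adjusted p = 0.948 with an estimated correlation). The cell division and histone list, with none of 47 genes called, was lower in rank (median -0.01, camera adjusted p = 0.0377, from 0.0296 to 0.103 over 11 alternatives, adjusted p = 0.948 with an estimated correlation). The share of higher calls was 78.5% as deposited, 50.2% after median-of-ratios scaling (565 higher, 560 lower) and 48.2% after quantile normalization (475 higher, 510 lower). Without NahG Pta replicate 2 there were 686 calls.

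In tga plants MpPOD98 rose with infection at 24 h from 1.46 ± 0.248 to 4.43 ± 0.73 TPM (log2 change 1.14, SE 0.14, n = 3, limma adjusted p = 0.000301) and the cell wall genes MpGH16.17 (Mp3g10400) and MpGH16.16 from 4.64 ± 1.4 to 9.5 ± 1.13 TPM and from 6.24 ± 1.25 to 11.4 ± 1.61 TPM. MpPPO22 (Mp5g18380) fell from 75.7 ± 11.9 to 32.1 ± 5.09 TPM (-1.21, SE 0.23, limma adjusted p = 0.00522), MpPKC2 (Mp2g06680) from 20.5 ± 0.484 to 10.6 ± 1.24 TPM and MpABCC13 from 10.5 ± 0.418 to 6.79 ± 0.858 TPM. MpFTPSL8, at 2.72 TPM in mock and 7.43 TPM in infected tga plants, was not called (limma adjusted p = 0.0687), with a log2 change of 1.16 against 1.09 in Tak-1. The largest fall of a named gene was less firm: MpDIR39 (Mp5g16510) went from 12.8 ± 2.78 to 1.29 ± 0.364 TPM (-2.59, limma adjusted p = 0.0325), a call lost without each single library (adjusted p from 0.073 to 0.108). Of the 12545 genes 236 were called, 100 higher and 136 lower, and 3 rose and 13 fell by at least 1 log2 unit. Of 112 peroxidases 11 rose and none fell (22 and 1 adjusted over the list alone, median 0.17, camera adjusted p = 5.35e-08, adjusted p = 0.686 with an estimated correlation). One was MpPOD7 (Mp2g03340), from 22.4 ± 2.99 to 31.9 ± 1.34 TPM. Of 77 cell wall genes 4 rose and none fell (13 and 1 adjusted over the list alone, camera adjusted p = 0.00983, adjusted p = 0.986 with an estimated correlation). The 236 calls became 129, 142 and 117 without tga mock replicate 1, 2 or 3, and 93 and 138 without tga Pta replicate 1 or 2.

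**Figure D2:**
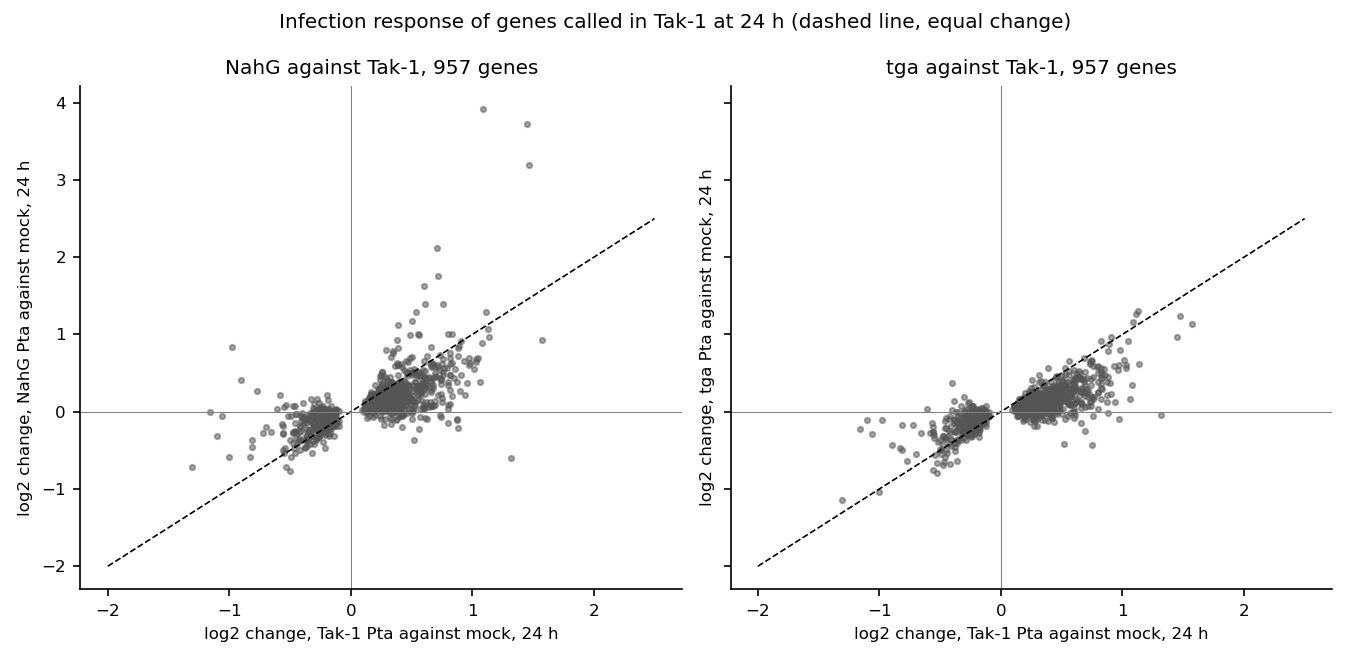
Log2 change with infection at 24 h in NahG (left) and tga plants (right) against that in Tak-1, over the 957 genes called in Tak-1, with a dashed line where both are equal. Slopes through these points were 0.6 for NahG and 0.5 for tga.

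The responses of the lines were then set against each other. Over the 957 genes called in Tak-1 at 24 h, 865 (90.4%) changed with the same sign in NahG plants, with a slope of 0.6 on the Tak-1 change, and 857 (89.6%) in tga plants, with a slope of 0.5. These genes were chosen on the Tak-1 values, which lowers both slopes. Over the 1155 genes called in NahG the slope was 1.26, and over the 236 genes called in tga 1.06, a choice of genes that raises the slopes in turn. In all, 356 genes were called in both Tak-1 and NahG in the same direction and 138 in both Tak-1 and tga. Genes are not independent replicates, so no p-value is given for these slopes.

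The difference in response between NahG and Tak-1 plants was called for 39 genes, 31 more positive and 8 more negative in NahG (limma interaction test). MpFTPSL8 led, with a difference of 2.83 (SE 0.45, limma adjusted p = 0.00948), and kept its call without each single library. The P450 gene MpCYP822B1 (Mp5g09470) went from 11.8 ± 0.977 to 26.7 ± 2.56 TPM in NahG and from 14.6 to 17.5 TPM in Tak-1 (difference 0.88, limma adjusted p = 0.011, but 0.0509 without NahG Pta replicate 2 and from 0.00654 to 0.0509 without single libraries). No cell wall gene was called, but the cell wall list (median difference -0.09, camera adjusted p = 2.99e-05) and the polyphenol oxidases (median -0.14 but mean 0.01, camera adjusted p = 0.00222) ranked lower in NahG as lists, and neither passed with an estimated correlation (adjusted p = 0.269 for both). Of the peroxidases 3 were called more positive, against a lower list (median -0.15, camera adjusted p = 3.16e-06). WRKY factors were higher as a list with no gene called (median 0.21, camera adjusted p = 0.00258, from 0.000143 to 0.0608 over 11 alternatives). With an estimated correlation peroxidases and WRKY factors had adjusted p = 0.403 and 0.436. The share of positive differences was 79.5% as deposited, 55.1% (27 against 22) after median-of-ratios scaling and 55.3% (21 against 17) after quantile normalization. The 39 calls became 9 without Tak-1 Pta replicate 1, 11 without NahG Pta replicate 1 or 2, 21 and 23 without NahG mock replicate 2 or 1, 23 without Tak-1 mock replicate 3 and 81 without NahG Pta replicate 3. They were fewer with no filter, more with the stricter filter and the first pass, and many more in a fit of the compared groups alone (values in the section on the processing).

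Between tga and Tak-1 plants the difference in response was called for 6 genes, 1 more positive and 5 more negative in tga, with 1047 genes at an unadjusted p under 0.05. One was the GID1-like gene MpGID1L7 (Mp2g20050), at 62.5 TPM in mock and 57.4 TPM in infected tga plants against 60.2 and 68.2 TPM in Tak-1 (difference -0.3, limma adjusted p = 0.0478). Polyphenol oxidases had a lower response in tga plants as a list, and this passed with an estimated correlation too (median -0.23, camera adjusted p = 3.68e-05, adjusted p = 0.0414 with an estimated correlation). A difference of responses also depends on the mock level. In mock plants the 3 called members picked by the rule were higher in tga than in Tak-1. MpPPO71 stood at 53 ± 1.61 against 29.2 ± 0.832 TPM (0.84, limma adjusted p = 2.54e-05), MpPPO54 at 45.5 against 30.1 TPM and MpPPO42 at 136 against 102 TPM. The list did not pass between these mock plants. For the difference of responses none of its 36 genes was called over all genes, and 8 were lower adjusted over the list alone. Nutrient transporters (median -0.12, camera adjusted p = 0.0052, adjusted p = 0.309 with an estimated correlation), peroxidases (-0.1, camera adjusted p = 0.007) and P450 genes (-0.06, camera adjusted p = 0.0196) were lower as lists, each up to 0.0994 over 11 alternatives. Dirigent proteins (-0.12, camera adjusted p = 0.0363), oxylipin genes (-0.18, camera adjusted p = 0.042) and pathogenesis-related genes (-0.1, camera adjusted p = 0.042) were lower too, up to 0.0994, 0.101 and 0.0994, and cell division genes higher (0.08, camera adjusted p = 0.00569). With an estimated correlation these lists, from peroxidases on, had adjusted p = 0.651, 0.309, 0.651, 0.651, 0.662 and 0.651. The count of 6 was 0 without Tak-1 mock replicate 2 or 3, Tak-1 Pta replicate 1 or 2, tga mock replicate 2 or 3, or tga Pta replicate 1 or 2, was 2 without Tak-1 mock replicate 1 and 1 without Tak-1 Pta replicate 3. No gene was called with a pseudocount of 0.1 or with the stricter filter. More were called after quantile normalization and in a fit of the compared groups alone (values in the section on the processing).

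Between tga and NahG plants 121 genes differed in response, 5 more positive and 116 more negative in tga. After median-of-ratios scaling the split was 9 against 74, and after quantile normalization 5 against 41. MpPOD89 was at 12.8 ± 1.15 TPM in mock and 14.3 ± 1.16 TPM in infected tga plants, against 9.89 and 104 TPM in NahG (difference -3.05, SE 0.51, limma adjusted p = 0.00546). MpFTPSL8 had a difference of -2.76 (limma adjusted p = 0.00503). WRKY factors were lower as a list in tga plants (median -0.27, 1 of 13 called lower, 7 adjusted over the list alone, camera adjusted p = 7.07e-06, adjusted p = 0.679 with an estimated correlation), and so were pathogenesis-related genes (6 of 68 lower, 12 adjusted over the list alone, median -0.13 and mean -0.62, camera adjusted p = 0.0071, up to 0.0791 over 11 alternatives, adjusted p = 0.854 with an estimated correlation). Phenylpropanoid genes (median -0.2) and dirigent proteins and laccases (-0.11) had camera adjusted p = 0.0267 and 0.0404, up to 0.0667 and 0.154, while cell wall genes, with 1 of 77 called and a median of 0.01, ranked higher than other genes (camera adjusted p = 0.0071). With an estimated correlation these 3 lists had adjusted p = 0.854. The count of 121 became 32 and 35 without NahG Pta replicate 2 or 1, 39 and 68 without NahG mock replicate 2 or 1, 78, 37 and 64 without tga mock replicate 1, 2 or 3, and 39, 42 and 73 without tga Pta replicate 1, 2 or 3. In a fit of the compared groups alone the count was higher (value in the section on the processing).

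**Figure D3:**
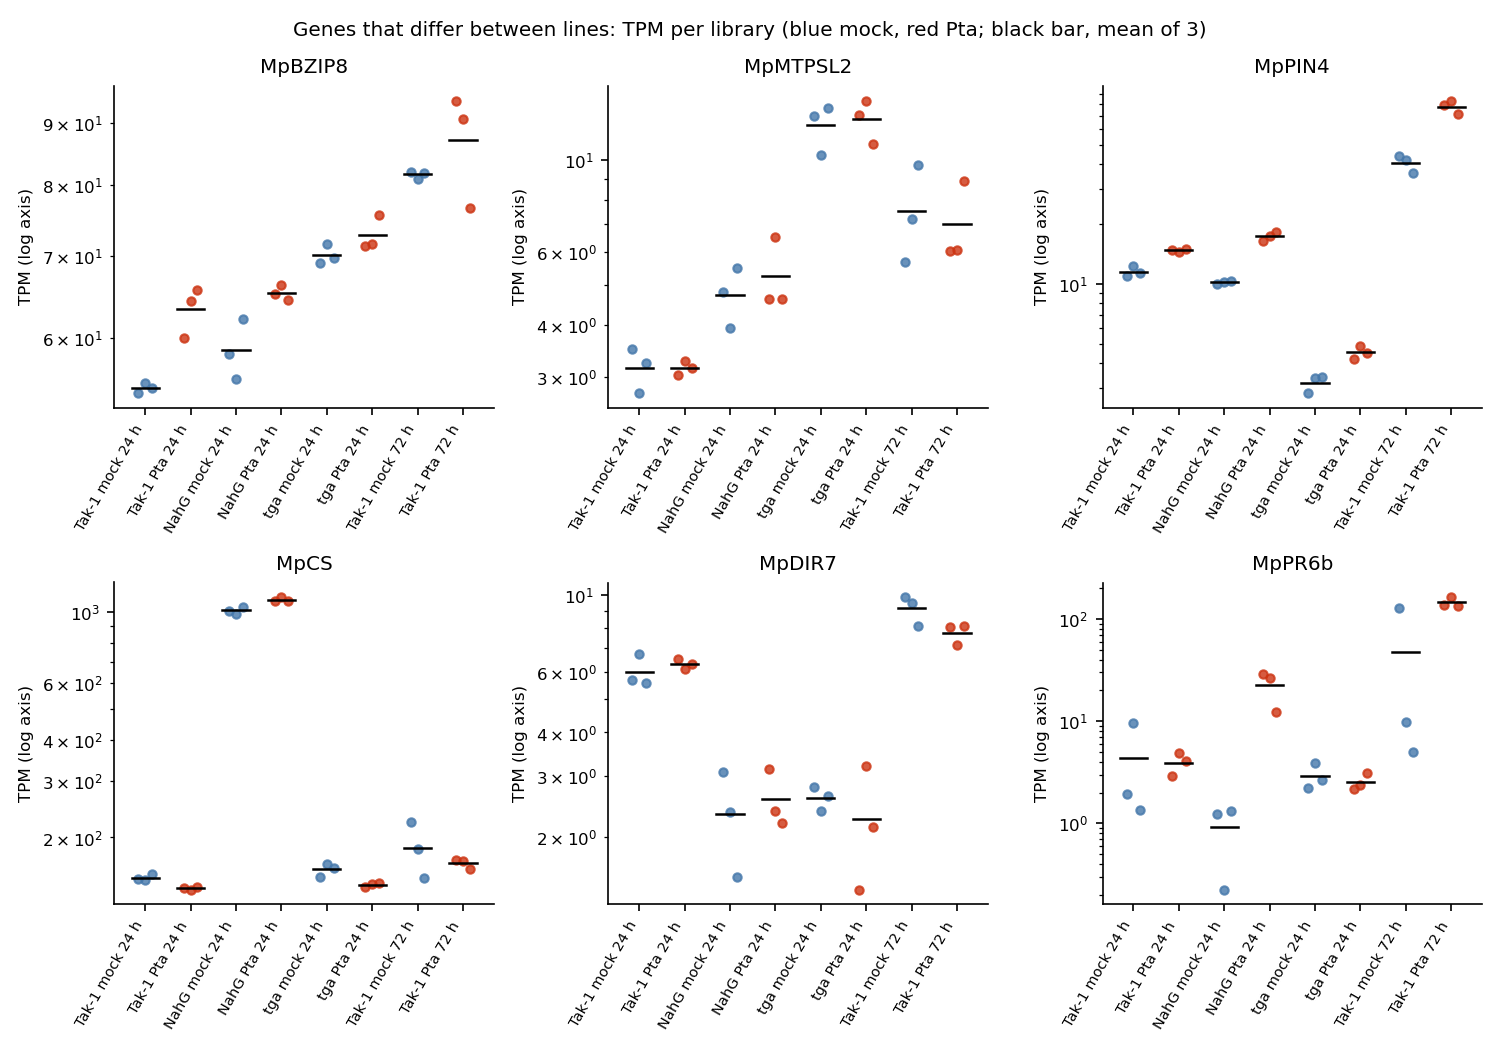
TPM on a log axis of 6 genes that differ between lines, in each of the 24 libraries (blue, mock; red, Pta), with a black bar at the mean of 3 libraries. MpCS stood at 1010 TPM in mock NahG plants against 150 TPM in mock Tak-1, and MpPIN4 at 3.21 TPM in mock tga plants against 11.6 TPM.

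How NahG plants differ from the wild type before infection was asked in the mock groups at 24 h. Among named genes 1 stood out: MpCS (Mp3g00560) was at 1010 ± 25.3 TPM in NahG and 150 ± 3.17 TPM in Tak-1 (log2 difference 2.74, SE 0.08, n = 3, limma adjusted p = 1.83e-15). Its neighbour Mp3g00570, which has no symbol and lies outside the rule for named genes, was higher too (106 ± 1.47 against 13.7 ± 0.693 TPM). MpBZIP9 (Mp6g03920) (17.8 ± 3.56 against 10.2 ± 0.743 TPM) and MpDOXC20 (Mp3g19390) (17.4 ± 2.07 against 9.97 ± 0.765 TPM) were higher. The dirigent genes MpDIR7 (Mp6g09540) (2.32 ± 0.769 against 5.99 ± 0.639 TPM, -1.1, limma adjusted p = 0.000246) and MpDIR9 (Mp3g22420) (48.5 ± 4.97 against 94.1 ± 5.23 TPM) were lower, as was MpPOD161 (Mp7g19390) (10.4 ± 1.18 against 21.3 ± 1.78 TPM). In all 753 genes were called, 475 higher and 278 lower, with 5 higher and 12 lower by at least 1 log2 unit.

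Of 50 dirigent and laccase genes 8 were lower and 2 higher in mock NahG plants (median -0.04, camera adjusted p = 0.000868, adjusted p = 0.949 with an estimated correlation). Of 5 heat shock genes 3 were higher and none lower (4 higher adjusted over the list alone), with MpHSP90-1 (Mp1g26610) at 591 ± 24 against 469 ± 9.36 TPM (camera adjusted p = 0.0102, adjusted p = 0.949 with an estimated correlation). Of 47 cell division and histone genes 3 were lower, with MpH2A.X.1 (Mp2g00760) at 322 ± 4.85 against 355 ± 3.03 TPM (camera adjusted p = 0.0102, adjusted p = 0.949 with an estimated correlation). Of 68 pathogenesis-related genes 3 were lower and 1 higher (camera adjusted p = 0.0138, from 0.000852 to 0.212 over 11 alternatives, adjusted p = 0.949 with an estimated correlation), among them MpGH19.4 (Mp4g01780) at 9.17 ± 0.314 against 13.6 ± 0.231 TPM. The balance turned with scaling: 63.1% of calls were higher as deposited, 36.4% (244 higher, 427 lower) after median-of-ratios scaling and 43% (275 higher, 364 lower) after quantile normalization. The 753 calls became 366 and 437 without Tak-1 mock replicate 1 or 3 and 370 without NahG mock replicate 1.

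In infected plants at 24 h MpCS was again far higher in NahG, at 1090 ± 17.8 against 140 ± 1.59 TPM (log2 difference 2.96, limma adjusted p = 4.02e-16). MpPR6a (Mp8g09630) stood at 12.1 ± 5.91 against 1.18 ± 0.175 TPM (2.46, SE 0.57, limma adjusted p = 0.00538), MpPR4 at 53.8 ± 15.6 against 9.57 ± 0.818 TPM (2.33, limma adjusted p = 0.00414) and MpFTPSL8 at 32.5 ± 8.38 against 7.7 ± 1.09 TPM (1.92, limma adjusted p = 0.000409). MpExpansin6 (171 ± 5.39 against 285 ± 1.31 TPM), MpPL1.3 (131 ± 4.75 against 203 ± 9.54 TPM) and MpUGT11 (Mp2g23900) (13.2 ± 1.76 against 27.4 ± 2.1 TPM, -1.01, limma adjusted p = 2.04e-06) were lower. Of the 12545 genes 2389 were called, 1901 higher and 488 lower, with 56 higher and 13 lower by at least 1 log2 unit.

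Polyphenol oxidases were lower in infected NahG than in infected Tak-1 plants (0 of 36 higher, 5 lower, 4 adjusted over the list alone, median -0.1), and the list passed with an estimated correlation too (camera adjusted p = 1.07e-05, adjusted p = 0.0346 with an estimated correlation). MpPPO37 (Mp6g17780) stood at 37.3 ± 0.653 against 47.1 ± 1.76 TPM. Of 77 cell wall genes 7 were lower and 2 higher (6 and 2 adjusted over the list alone, camera adjusted p = 2.47e-06, adjusted p = 0.136 with an estimated correlation). Of 112 peroxidases 6 were lower and 7 higher, and the list test was lower (median -0.05, camera adjusted p = 2.27e-05, from 5.04e-06 to 0.104 over 11 alternatives, adjusted p = 0.48 with an estimated correlation). Heat shock genes were higher (4 of 5, camera adjusted p = 0.0289, from 0.012 to 0.0661 over 11 alternatives, adjusted p = 0.519 with an estimated correlation). The cupins, a list added after the data were seen, were lower (4 of 45 lower, 2 higher, camera adjusted p = 0.00025, from 5.21e-05 to 0.103 over 11 alternatives, adjusted p = 0.151 with an estimated correlation). Dirigent and laccase genes tested lower (5 lower, 3 higher, median -0.02 but mean 0.02, camera adjusted p = 0.00522, from 0.00274 to 0.338 over 11 alternatives, adjusted p = 0.614 with an estimated correlation). Here too the balance turned with scaling: 79.6% of calls were higher as deposited, 34.5% (539 higher, 1023 lower) after median-of-ratios scaling and 40.3% (598 higher) after quantile normalization, and the total of 2389 became 1562 and 1485. Without Tak-1 Pta replicate 1 there were 1201 calls, and without NahG Pta replicate 1 or 3 there were 1453 and 1492.

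In mock tga plants at 24 h the unnamed gene Mp7g01940 was at 5880 ± 232 TPM against 139 ± 6.77 TPM in Tak-1 (log2 difference 5.39, SE 0.04, n = 3, limma adjusted p = 2.72e-27). The terpene synthase-like gene MpMTPSL2 (Mp3g18500) (12.1 ± 1.62 against 3.16 ± 0.383 TPM, 1.65, limma adjusted p = 1.15e-06), the LEA-like gene MpLEA-like45 (Mp6g03120) (70.4 ± 6.41 against 29.7 ± 4.14 TPM) and the NPF transporter MpNPF24 (Mp5g08940) (6.15 ± 0.597 against 2.19 ± 0.308 TPM) were higher. MpPIN4 (Mp5g05150), of the PIN auxin efflux carriers, was lower, at 3.21 ± 0.325 against 11.6 ± 0.743 TPM (-1.58, SE 0.07, limma adjusted p = 6.61e-12), as were MpPOD73 (Mp5g04320) (6.96 ± 2.47 against 15.1 ± 0.233 TPM) and MpDIR9 (50.7 ± 1.59 against 94.1 ± 5.23 TPM). In total 1168 genes were called, 786 higher and 382 lower, with 49 higher and 5 lower by at least 1 log2 unit.

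Genes of abscisic acid response and LEA proteins formed the largest group: 48 of 98 were higher and 2 lower in mock tga plants (51 and 7 adjusted over the list alone, median 0.24, camera adjusted p = 2.18e-14, adjusted p = 0.0609 with an estimated correlation). The dehydrin MpDHN1 (Mp6g07540) was at 58 ± 3.8 against 29.3 ± 1.66 TPM and MpLEA2 (Mp6g13390) at 55.6 ± 3.68 against 26.1 ± 2.8 TPM, while MpABA1 (Mp2g00670), at 306 against 303 TPM, was not called. Of 15 terpene synthase genes, a marker list of oil body cells, 6 were higher and none lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.00738, adjusted p = 0.0609 with an estimated correlation), with MpFTPSL2 (Mp6g04320) at 18.8 ± 1.18 against 9.24 ± 0.954 TPM. Of 37 nutrient transporters 9 were higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 0.000345, adjusted p = 0.12 with an estimated correlation). Of 112 peroxidases 11 were lower and 4 higher (17 and 4 adjusted over the list alone, camera adjusted p = 0.00738, from 0.00113 to 0.0531 over 11 alternatives, adjusted p = 0.777 with an estimated correlation). Of 76 P450 genes 17 were higher and 1 lower (21 and 3 adjusted over the list alone, camera adjusted p = 0.0434, from 0.0161 to 0.23 over 11 alternatives, adjusted p = 0.345 with an estimated correlation). The share of higher calls was 67.3% as deposited, 56% (743 higher, 583 lower) after median-of-ratios scaling and 51.1% (616 higher, 589 lower) after quantile normalization. Without Tak-1 mock replicate 2 there were 756 calls.

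Between infected plants of tga and Tak-1, Mp7g01940 was at 6350 ± 163 against 134 ± 2.89 TPM (log2 difference 5.55, limma adjusted p = 1.49e-27), MpMTPSL2 at 12.5 ± 1.49 against 3.16 ± 0.121 TPM and MpDHN1 at 70.8 ± 13.8 against 32 ± 3.03 TPM. MpPIN4 was lower, at 4.55 ± 0.349 against 14.8 ± 0.232 TPM (-1.51, limma adjusted p = 1.66e-11), and so were MpPOD73 (10.3 ± 1.41 against 23.5 ± 1.92 TPM) and MpPOD92 (Mp5g10750) (1.76 ± 0.44 against 5.25 ± 1.06 TPM). Calls came to 1092 genes, 640 higher and 452 lower, with 56 higher and 10 lower by at least 1 log2 unit. After median-of-ratios scaling and quantile normalization 48% were higher (589 against 637 and 583 against 631) instead of 58.6%.

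Of 98 genes of abscisic acid response and LEA proteins 51 were higher and 2 lower in infected tga plants (52 and 5 adjusted over the list alone, median 0.53), and the list passed with an estimated correlation too (camera adjusted p = 6.36e-19, adjusted p = 0.0217 with an estimated correlation). So did the terpene synthases (6 of 15 higher, none lower, median 0.25, camera adjusted p = 0.00146, adjusted p = 0.0217 with an estimated correlation). Of 112 peroxidases 23 were lower and 1 higher (33 and 2 adjusted over the list alone, median -0.19, camera adjusted p = 3.74e-08, adjusted p = 0.239 with an estimated correlation). Pathogenesis-related genes were lower (5 of 68, camera adjusted p = 0.0126), with MpGH18.2 (Mp2g01600) at 3.31 ± 0.911 against 6.4 ± 0.488 TPM, and so were receptor kinases (4 of 78 lower, 1 higher, camera adjusted p = 0.0126), while cell division and histone genes were higher (3 of 47, 6 adjusted over the list alone, camera adjusted p = 0.00923), with MpH4g (Mp5g22460) at 37.8 ± 3.53 against 28.4 ± 1.97 TPM. These 3 lists had adjusted p = 0.888 with an estimated correlation. Cell wall genes (9 of 77 lower, 2 higher) and polyphenol oxidases (7 of 36 lower, 3 higher) had camera adjusted p = 0.0324 and 0.0386, up to 0.0901 and 1 over 11 alternatives, and adjusted p = 0.786 and 0.427 with an estimated correlation.

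**Figure D4:**
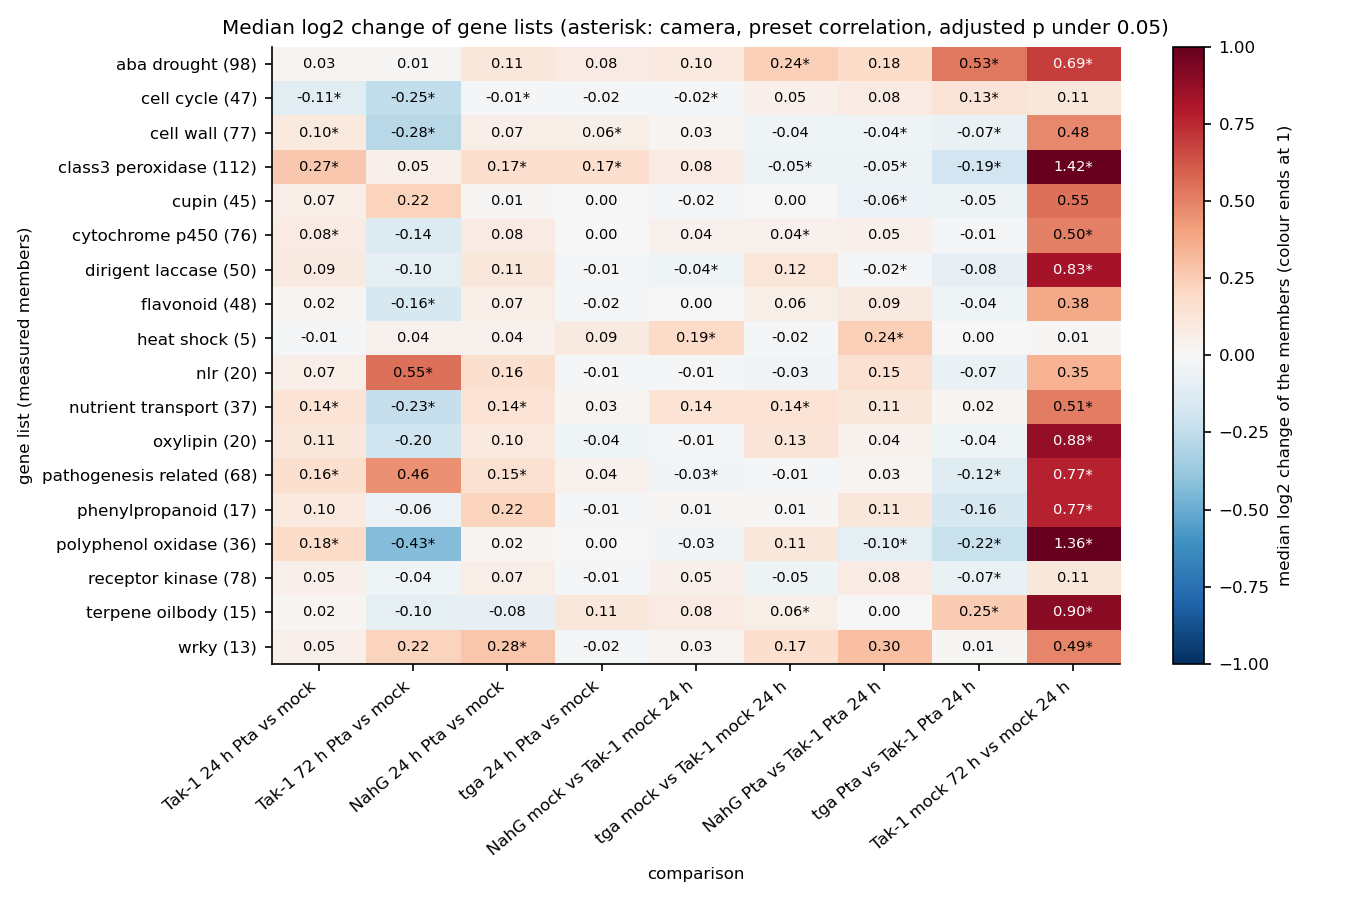
Median log2 change of 18 gene lists (rows) in 9 comparisons (columns), coloured from lower to higher, with an asterisk where camera gave an adjusted p under 0.05. The abscisic acid and LEA list had medians of 0.24 and 0.53 in tga against Tak-1, and the peroxidases a median of 1.42 between mock plants at 72 h and 24 h.

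The differences of the 2 lines from Tak-1 overlapped in part. In mock plants 95 genes were higher and 55 lower in both NahG and tga, and 24 were called in opposite directions, where independent lists would share 29.8 and 8.47. MpDIR7 and MpDIR9 were among the genes lower in both. In infected plants 231 were higher and 149 lower in both and 24 opposite, against 97 and 17.6. The correlation across the 12545 genes was 0.23 in mock and 0.31 in infected plants. Shared Tak-1 libraries alone gave 0.5 in 100 simulated pairs of groups with no effects. That value is set by the design, and effects that the lines do not share lower it, so the lower observed values do not measure the overlap. The covariance was 0.00906 in mock plants against a simulated mean of 0.00735 and a highest value of 0.00873. In infected plants it was 0.0155, against 0.00734 and 0.00836. Part of the overlap could come from the shared libraries. In a test chosen after these results were seen, the Tak-1 libraries were shared out, 1 for a line and the others for the second line, in all 6 ways, which also lowers the number of calls. In mock plants 4 to 25 genes were then higher and 9 to 18 lower in both lines (5 to 17 opposite), where independent lists would share 2.82 to 9.23 and 0.599 to 2.05, and the covariance ran from -0.00076 to 0.00521. With Tak-1 mock replicate 3 alone set against NahG, 4 genes were higher in both, where independent lists would share 4.02. In each other way the genes higher in both exceeded that expectation. In infected plants 42 to 72 were higher and 33 to 65 lower in both (6 to 15 opposite), against 9.56 to 42.2 and 2.09 to 6.97, with a covariance from 0.00631 to 0.0116.

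**Figure D5:**
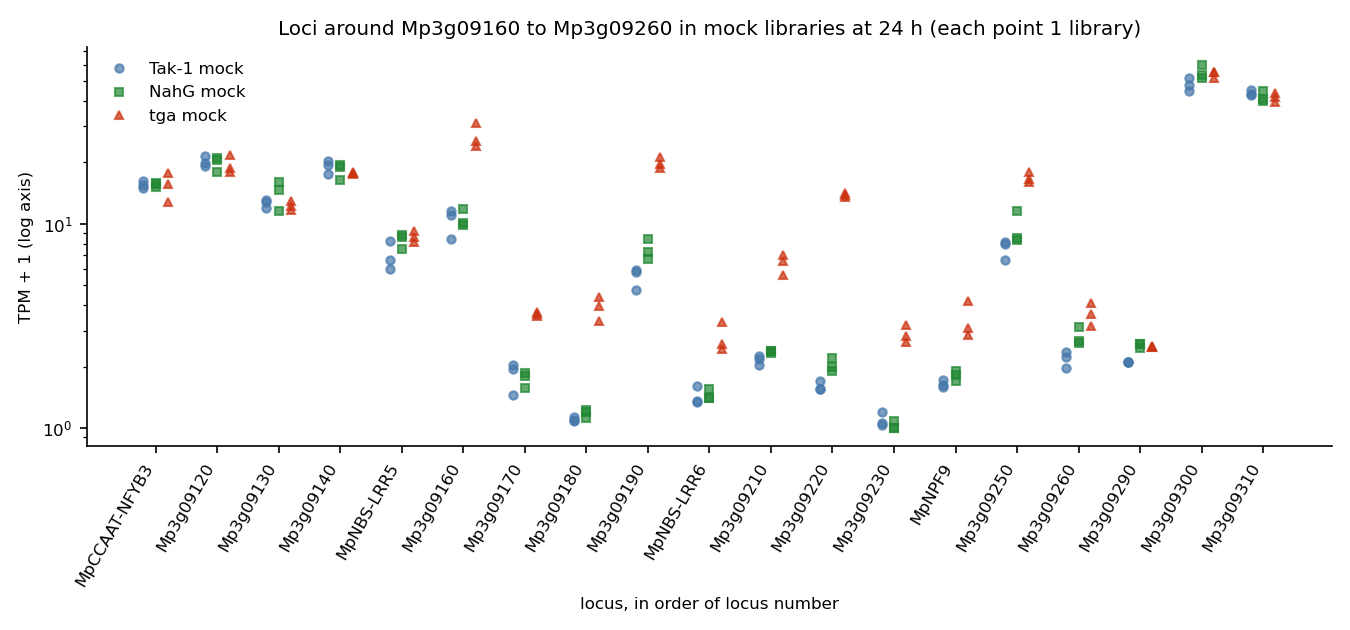
TPM + 1 on a log axis over neighbouring tested genes of 1 region, in mock libraries of Tak-1, NahG and tga at 24 h. From Mp3g09160 to Mp3g09260 the tga libraries lie above those of both other lines.

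A run of 11 neighbouring tested genes, from Mp3g09160 to Mp3g09260, was higher in tga than in Tak-1 plants in both treatments, by 0.73 to 3.11 log2 units in mock and 0.69 to 3.02 in infected plants. The run holds the NLR gene MpNBS-LRR6 and the transporter gene MpNPF9 (Mp3g09240), at 2.37 ± 0.708 against 0.641 ± 0.0612 TPM. These genes were singled out after their values were seen.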

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

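The tests on the 11 neighbouring genes, on the genes around MpCS and on the mock plants at 72 h were chosen only after the results were seen, while the counts over other splits of the samples were planned. The tests of whether a split turned round a response were also chosen after.

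The infection responses of lines or times differed by a test of the difference for the results below. Between NahG and Tak-1 39 genes were called, including MpFTPSL8 (difference 2.83), MpPOD89 (2.51), MpGH18.1 (1.35), MpPOD167 (0.93), MpCYP822B1 (0.88) and MpMATE15 (0.64). The mean of MpPOD167 went from 10.9 to 17.6 TPM in NahG and from 18.1 down to 14.5 TPM in Tak-1. That of MpMATE15 went from 4.17 to 5.97 TPM in NahG and from 6.07 down to 5.11 TPM in Tak-1. The lists that differed were cell wall genes (median -0.09), peroxidases (-0.15), polyphenol oxidases (-0.14) and WRKY factors (0.21), by camera with the preset correlation, and none passed with an estimated correlation (adjusted p = 0.269, 0.403, 0.269 and 0.436) or by fry. Of these genes only MpFTPSL8 kept its call without each single library, and MpPOD89, MpPOD167 and MpMATE15 lost it without 10, 9 and 9 of 12. Between tga and Tak-1 6 genes were called, MpGID1L7 (-0.3) among them. The lists were cell division genes (0.08), peroxidases (-0.1), P450 genes (-0.06), dirigent and laccase genes (-0.12), nutrient transporters (-0.12), oxylipin genes (-0.18), pathogenesis-related genes (-0.1) and polyphenol oxidases (-0.23), of which only the last passed with an estimated correlation (adjusted p = 0.0414) and by fry. MpGID1L7 lost its call whichever of the 12 libraries was left out. Between tga and NahG 121 genes were called, including MpPL1.3 (0.33), MpDIR35 (-2.49), MpGH19.6 (-2.74), MpFTPSL8 (-2.76), MpPR4 (-3.04), MpPOD89 (-3.05) and MpPR15h (-3.46). The lists were cell wall genes (0.01), dirigent and laccase genes (-0.11), pathogenesis-related genes (-0.13), phenylpropanoid genes (-0.2) and WRKY factors (-0.27), and none passed with an estimated correlation (adjusted p = 0.679 for WRKY factors and 0.854 for the others). MpFTPSL8 and MpPOD89 kept their calls without each single library, while MpPL1.3, MpGH19.6, MpDIR35, MpPR15h and MpPR4 lost them without 2, 5, 10, 10 and 11 of 12.

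Between 72 h and 24 h in Tak-1 6047 genes were called, including MpPR1w (4.3), MpNBS-LRR11 (3.38), MpRLK-Pelle_L-LEC26 (3.3), MpFTPSL8 (3.18), MpGST38 (2.88), MpPR1l (2.86), MpPTB3 (-1.85), MpOMT13 (-1.87), MpLOX8 (-1.91), MpPTB4 (-2.11), MpDIR61 (-2.55) and MpLOX4 (-3.1). The lists were cell wall genes (-0.35), peroxidases (-0.38), P450 genes (-0.26), flavonoid genes (-0.21), NLR genes (0.6), nutrient transporters (-0.41) and polyphenol oxidases (-0.73). All named genes kept their calls without each single library. Of the lists, peroxidases (camera adjusted p = 0.00645, from 1.16e-05 to 0.0878 over 11 alternatives, adjusted p = 0.58 with an estimated correlation), P450 genes (0.0163, from 0.0106 to 0.0553, and 0.212), flavonoid genes (0.0347, from 0.0137 to 0.0828, and 0.58) and NLR genes (0.0283, from 0.00806 to 0.0855, and 0.613) lost their pass in some alternatives. Nutrient transporters (0.000345, from 0.000342 to 0.0273, and 0.136) and cell wall genes (2.69e-07, from 3.3e-08 to 4.82e-05, and 0.087) did so only with an estimated correlation, and polyphenol oxidases alone passed with it (0.0174).

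The counts were set against other splits of the same libraries. For the 9 comparisons of 3 against 3 libraries the 10 possible splits are too few for a share under 0.05, and only the real split gave as many genes (1 of 10). In 7 of them no other split called a gene, and the highest other counts were 97 of the real 7431 in Tak-1 at 72 h and 18 of the real 6976 between mock plants. For the differences of responses 100 splits were drawn. As many genes as the real 39, 6 and 121 were given by 12, 9 and 7 of them, the real one included, with highest other counts of 2175, 598 and 805. For the 6047 genes between times 2 splits gave as many, the highest other 6075. These high counts point to a structure of the samples: 8, 5, 5 and 1 of the other splits as large had most or all labels of 1 response turned round, which tests the sum of the responses. The shares of splits therefore do not measure chance, which is left open for the counts between lines. Of the 48, 47, 43 and 48 other splits without such a turn 3, 3, 1 and 0 gave as many genes, and the highest counts were 71, 55, 131 and 5486.

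The block of 11 neighbouring genes from Mp3g09160 to Mp3g09260 was higher in tga plants in both treatments, by 0.73 to 3.11 log2 units in mock plants. Displaced decimal marks are argued against by all 12 columns compared adding up to 1000000, and scaling by all 11 genes staying called after median-of-ratios scaling. Part of these sums was reached by the restoration itself. Tak-1 replicates 2 and 3 in both treatments, mock tga replicate 3 and infected tga replicate 1 each needed 1 changed cell. In 0 of 1000 shuffles of the genes did scattered independent differences lie side by side in a run as long, the longest being 5, while the longest runs in NahG were 4 genes lower in mock plants (Mp2g07480 to Mp2g07510, 28 of 1000 shuffles) and 5 higher in infected plants (537 of 1000). Loss of TGA function cannot be told apart from a second change in the 1 tga line sampled, since 0 of the loci were called higher in NahG plants in both treatments (log2 differences from -0.09 to 0.45 in mock NahG) and no second tga line was analysed here. A change of the chromosome region carried by this line, rather than of its single genes, is a hypothesis that may be followed up, and it was not tested.

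The second pattern lies around MpCS in NahG plants, where Mp3g00550 fell from 14.7 ± 0.871 to 4.67 ± 0.363 TPM in mock plants, MpCS rose from 150 ± 3.17 to 1010 ± 25.3 TPM and Mp3g00570 from 13.7 ± 0.693 to 106 ± 1.47 TPM. A displaced mark is argued against by all 6 mock columns adding up to 1000000. Of these, Tak-1 replicates 2 and 3 and NahG replicate 1 added up only after the restoration changed 1 cell in each. The summed TPM of these genes went from 178 ± 4.7 to 1120 ± 26.4 TPM, a ratio of 6.28. Reads moved between the neighbours would keep their count, but not their summed TPM, which depends on gene length. Gene lengths and read counts were not available here, so the sum cannot exclude moved reads. Whether depletion of salicylate or an effect of the transgenic line is behind it cannot be told apart, because MpCS differed by 0.08 in mock tga plants, whose defect by their label is in a transcription factor and not in salicylate itself. An insertion of the overexpression construct near these genes may be a candidate explanation, and it was not tested.

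The third pattern is the spread of infection-responsive genes among the mock Tak-1 plants at 72 h: the mean log2 level of 91 genes that rose by at least 1 log2 unit in infected NahG plants was 4.33, 3.67 and 2.64 in the mock replicates, against 5.32, 5.45 and 5.21 in infected plants at 72 h. Scaling of the columns left the range as it was (1.01 of that before), and an infected sample labelled as mock is argued against by a gap of 0.87 between the lowest infected and the highest mock value, with an SD of 0.122 among infected samples. An infection-like response of different strength in the mock plants cannot be told apart from replicates at different points of the change with time. The difference of mock replicates 1 and 3 correlated across genes at 0.42 with the NahG response at 24 h (0.01 for the same difference at 24 h and 0.09 in infected plants at 72 h), but the change of mock plants from 24 h to 72 h did so at 0.41, and the genes of the score were chosen on the same response. In replicate 3, the lowest, 25 doubtful cells had been lowered in the restoration of the marks, and none of the mock columns at 72 h adds up to 1000000.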

How the results depend on the processing

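The alternatives named next were planned, except those with the first pass of the restoration, those without genes with an uncertain mark, those on the overlap in infected plants and those on slopes without single libraries, which were chosen after seeing the data. Asking for a log2 change of at least 1 left 18, 668, 92, 16, 17, 54, 69, 66, 15, 2, 37, 748 and 1090 genes (Tak-1 at 24 h and 72 h, NahG, tga, NahG and tga against Tak-1 in mock, then in infected plants, NahG less Tak-1, tga less Tak-1, tga less NahG, 72 h less 24 h, mock 72 h against 24 h). In NahG against Tak-1 infected plants the 2389 calls became 1562 after median-of-ratios scaling and 1485 after quantile normalization. The 39 calls of NahG less Tak-1 became 22 with no filter, 65 with the stricter filter, 67 with the first pass and 265 in a fit of the compared groups. The 6 of tga less Tak-1 became 0 with a pseudocount of 0.1 (limma, 1086 at an unadjusted p under 0.05), 2 with no filter, 0 with the stricter filter (865 unadjusted), 11 after quantile normalization, 1 with the replicate block, 10 with the first pass and 17 in a fit of the compared groups. The 121 of tga less NahG became 46 after quantile normalization, 75 in another alternative and 412 in a fit of the compared groups. The higher counts in fits of the compared groups come with another pooled spread: the median SD was 0.332 over 8 groups and 0.21 over 4 for 91 infection-responsive genes, and 0.0918 and 0.0843 for all 12545. Shared calls of both lines became 250 (mock) and 578 (infected) in a fit of all groups at 24 h, without those at 72 h. With an estimated correlation 7 of 78 list calls held. Slopes for tga were 0.55 with a pseudocount of 0.1, 0.54 with the first pass and 0.56 in that fit at 24 h. For NahG they were 0.54 with a pseudocount of 5 and 0.55 after quantile normalization. The cause of these changes was not tested. Without single libraries the counts ran, in the same order, from 512 to 694, 6705 to 7400, 686 to 901, 93 to 170, 366 to 698, 756 to 958, 1201 to 1949, 751 to 886, 9 to 81, 0 to 9, 32 to 104, 5463 to 6261 and 6369 to 6650, the slopes from 0.44 to 0.54 (tga) and 0.45 to 0.61 (NahG), and the difference of MpBZIP8 in mock tga plants from 0.34 to 0.37. A library left out means fewer samples and, in its group, a spread taken from the others. All other counts stayed within 1.5 times. Replicate numbers did not pair the samples (the median correlation of deviations was 0, 3 of 84 pairs were over 0.1, and 8 of 24 libraries correlated best with their own number), and the replicate block changed no other count by 1.5 times. Of 425 results on named genes 7 lost and 1 gained a call with the block, and 24 lost and 5 gained one after quantile normalization. None of these results turned its direction. The values reported are those of the settings first described, with the revised restoration. The depth of the libraries is unknown, so its limit on low genes could not be given.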

Other observations

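Several lists hold called genes at 72 h without a pass as a list, in a comparison where 59.2% of all tested genes were called. Auxin and V chromosome genes were called less often than that. Of 140 genes of detoxification (glutathione S-transferases, glycosyltransferases and efflux transporters) 60 rose and 42 fell in infected Tak-1 at 72 h, and of 43 MYB factors 22 rose and 7 fell. Of 19 AP2/ERF factors 11 rose and 3 fell, and of 28 auxin genes 5 rose and 8 fell. None of these lists passed in that comparison (camera adjusted p = 0.698, 0.22, 0.361 and 0.376). Of 31 measured V chromosome genes 14 rose and 0 fell in infected Tak-1 at 72 h (camera adjusted p = 0.242).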
